A study of Homo sapiens with 12 samples.

How the data were processed

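HEK293T is a human embryonic kidney cell line that carries the SV40 large T antigen. Per the labels' protocols, the cells received DMSO (the vehicle control), the compound i14G1-10 at 20 µM or the compound i14G1-12 at 10 µM for 3 h. Lysates were then prepared for either of a pair of ribosome profiling assays. For Ribo-seq the cells received cycloheximide, which stalls elongating ribosomes. For Ti-seq they received harringtonine, which holds ribosomes at initiation sites, and cycloheximide. The values analysed here are not ribosome footprints. They come from messenger RNA captured with oligo(dT) beads from these lysates and made into bulk MARS-seq libraries, a method that sequences the 3' ends of polyadenylated transcripts. The compounds are known here by code name only, and the series title names them as inhibitors of the interaction of eIF1 with eIF4G1. There were 12 libraries: 3 treatments by 2 arms, with 2 libraries in each of the 6 groups. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

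The labels disagree on the treatment. The title and the description of a library name the same compound, but the treatment field names another in 8 of the 12 libraries and the same one in 4. By title there are 4 libraries each of Control, i14G1-10 and i14G1-12. By the treatment field, the Ti-seq libraries titled i14G1-10 received DMSO, the Ti-seq libraries titled Control and the Ribo-seq libraries titled i14G1-12 received i14G1-10, and the Ribo-seq libraries titled i14G1-10 received i14G1-12. The arm was taken from the title. Groups from the titles were fixed as the primary grouping, and groups from the treatment field as an alternative, before the data were examined. Because each grouping keeps the same pairs of libraries together and changes only the compound assigned to a pair, every comparison is given under both. No library was assigned to a compound from its values.

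The deposited values are a signal of normalized gene counts. Per the submitters' processing notes, the genome build was hg38 and bcl2fastq 2.17.1.14, cutadapt 1.8.3, STAR, HTSeq and DESeq2 were used; their roles and settings are not given in the sources used here. The table held 7417 genes and 12 libraries, with 7 further columns that were empty. It held 0 zero values. In every column all values lay within 0.01 of a whole multiple of a step (100% of values), so the gene counts behind them could be recovered. Every gene had at least 1 recovered count in every library, so a gene silent in any library is missing from the table, and strong losses to 0 cannot be seen. The recovered totals ran from 1128731 to 2769917 counts per library and cover the genes of the table only. Whether they count reads or molecular identifiers is not given in the sources used here. The deposited factors differed from median-ratio factors computed on this table by ratios of 0.95 to 1.13. The ratios were 0.952 to 1.01 in the Ribo-seq libraries and 1 to 1.13 in the Ti-seq libraries. The deposited scaling thus tended to set Ti-seq values lower against Ribo-seq values than median-ratio scaling would.

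Differences were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend and robust moderation, for the 6813 genes with a mean of at least 5 (604 genes were below it). The model had a mean for each of the 6 groups and 6 residual degrees of freedom, so all contrasts shared an estimate of the spread, even where groups differed in it. A compound effect is the mean of its differences within the arms, an arm effect the mean of the 3 within-compound differences, and a compound-by-arm term the Ti-seq difference minus the Ribo-seq difference. Tests were two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05, and log2 fold changes understate the change of genes with low values. Errors of fold changes are standard errors, and group values are normalized counts with their SD over 2 libraries.

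Of 30 gene lists fixed beforehand, 24 had at least 5 tested genes and were tested with camera (preset correlation 0.01), with an estimated correlation, and with fry. The lists of fibroblast, haematopoietic and keratin epithelial markers, of metallothioneins and of mitochondrially encoded mRNAs had 0 genes in the table, and the interferon and NF-kB list had 4, too few to test. The text names, for each of the 4 main comparisons, the 8 largest rises and 8 largest falls among called genes that moved the same way in both arms (for the arms, in all 3 compounds), up to 4 members of each list by smallest adjusted p, and in every comparison EIF1, EIF4G1, ATF4, DDIT3, ATF3, HSPA5 and PPP1R15A. Where no gene passed in a direction, the 3 with the smallest p are given as values. Only part of the list members so chosen are printed, and 1 gene that the rule names is not reported here.

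Gene positions are from GENCODE release 29 on hg38, matched by symbol for 7348 of the 7417 genes (99.1%). Symbols are as deposited, among them CYR61, now CCN1, and ATP5A1, now ATP5F1A.

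The settings varied were the pseudocount, the filter on low values, the scaling, the model (additive, library weights, without robust moderation, only the groups compared), the replicate number as a block, and each library left out in turn. Chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts, and the omission of the 2 libraries with most genes at 1 count. The count tests used 11 libraries, since the step of 1 column of the libraries titled i14G1-10 in the Ribo-seq arm was too close to 1 to be told from unscaled values by the check applied.

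On simulated counts for these genes and libraries, with known changes between the libraries titled i14G1-12 and Control in both arms, limma on 6801 genes recovered 48 of 50 genes raised by 2 log2 units, 47 of 49 lowered by 2, 37 of 50 raised by 1 and 17 of 50 lowered by 1, with 5 false calls. Halved transcripts were thus often missed. edgeR on 6890 genes recovered 48, 48, 38 and 23 of 50 with 9 false calls, and DESeq2 on 7129 genes 48, 42, 35 and 18 of 50 with 6 false calls. The simulated compound-by-arm test made 0 calls. Where 1 list was raised in the libraries titled i14G1-10, camera called it and 0 others for i14G1-10 against control. The simulation drew genes independently, with the same dispersion of a gene in every group and no arm effect. It therefore does not show how these tests behave with correlated genes or with groups that differ in spread.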

Results

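Oligo(dT)-captured messenger RNA of HEK293T cells was profiled in 12 MARS-seq libraries, 2 for each treatment in each of the Ribo-seq and Ti-seq arms. The comparisons ask how the input messenger RNA changed after 3 h with i14G1-10 (20 µM) or i14G1-12 (10 µM). They also ask how it differed between lysates made with and without harringtonine. Because titles and treatment field disagree for 8 libraries, each result is given for libraries grouped by title and by treatment field. Recovered gene counts per library ran from 1128731 (i14G1-10 Ti-seq 1 by title) to 2769917 (i14G1-12 Ribo-seq 1). The libraries with most genes at a count of 1 were i14G1-10 Ti-seq 1 (916 genes) and Control Ribo-seq 2 (475 genes). The first principal component held 51.1% of the variance and separated the arms. Between the 2 replicates of a group the chi-square per degree of freedom, set against counting error only, ran from 3.8 (titled i14G1-12, Ti-seq) to 26.7 (titled Control, Ribo-seq). Library weights estimated from the spread were equal within a group and ran from 0.474 (titled Control, Ribo-seq) to 2.58 (titled Control, Ti-seq). The groups thus differed in spread, while the main tests shared an estimate of it.

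EIF1 and EIF4G1, the genes of the factors named in the series title, were measured in every group. EIF1 (ENSG00000173812.10, chromosome 17, 41688885 to 41692668, hg38) stood between 2195 ± 77.7 normalized counts (libraries titled i14G1-12, Ribo-seq) and 3236 ± 118 (titled i14G1-12, Ti-seq). EIF4G1 (ENSG00000114867.20, chromosome 3, 184314495 to 184335358) stood between 319.9 ± 107 (titled i14G1-12, Ribo-seq) and 387.5 ± 57.4 (titled Control, Ribo-seq). HSPA5, the gene of the ER chaperone BiP, had group means of 3.344 to 11.01, and its changes are correspondingly imprecise. ATF4 (chromosome 22, 39519695 to 39522685), DDIT3 (chromosome 12, 57516588 to 57521737), ATF3 (chromosome 1, 212565334 to 212620777) and PPP1R15A (chromosome 19, 48872392 to 48876057) encode stress-response factors.

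**Figure D1:**
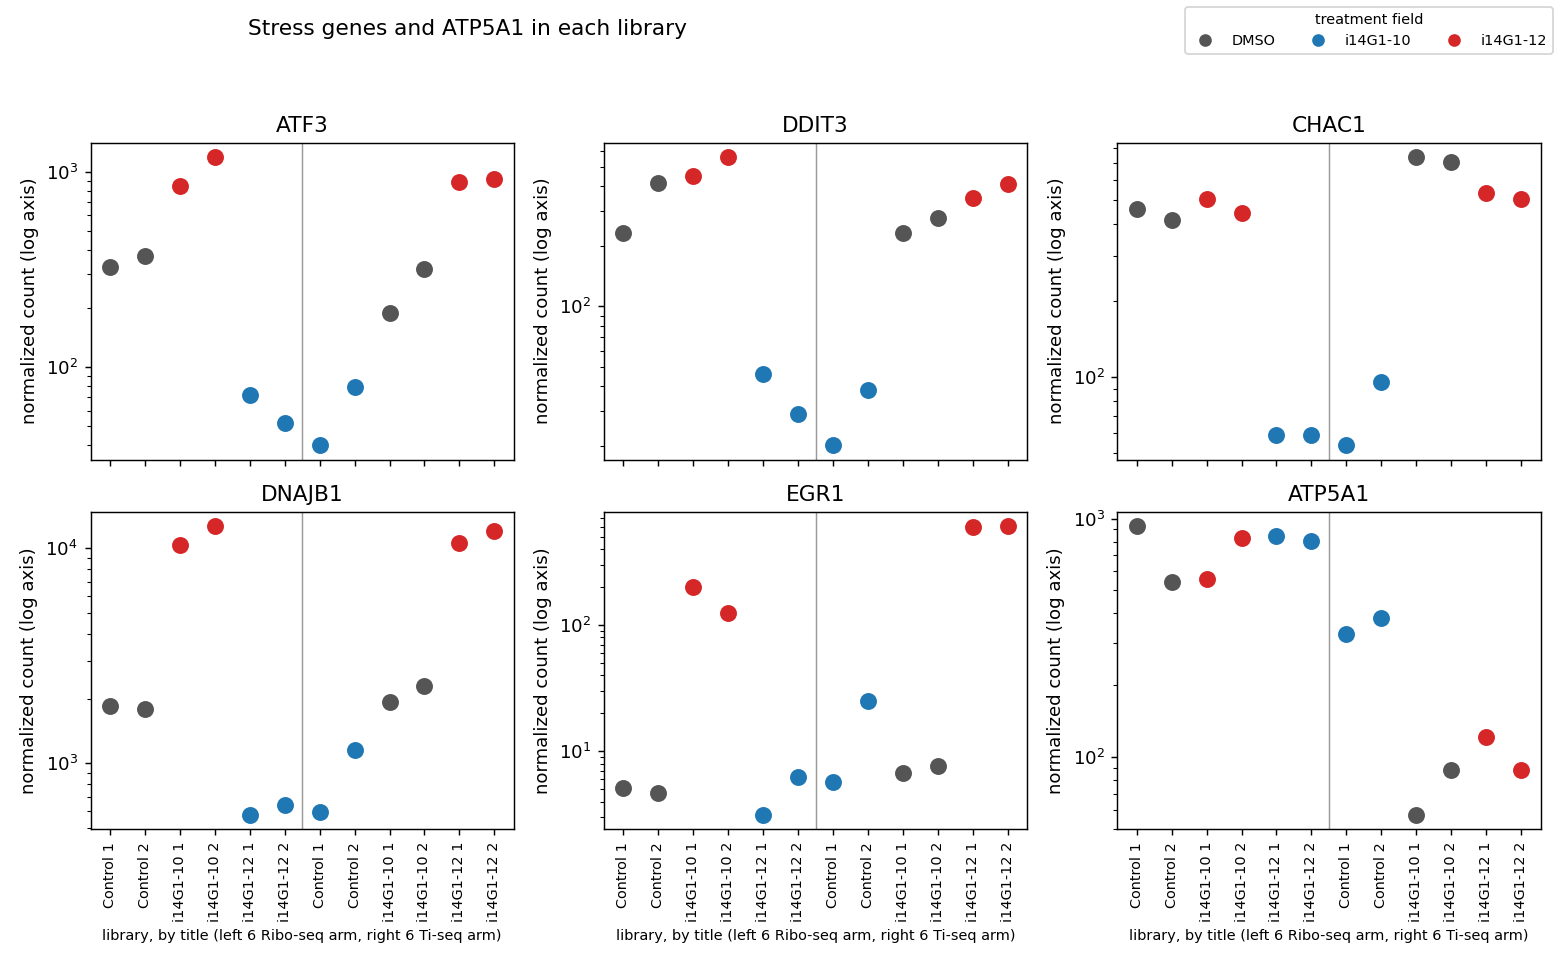
Normalized counts (log axis) of 6 genes in each of the 12 libraries, 1 point per library, placed by title with the Ribo-seq arm to the left of the line and the Ti-seq arm to the right, and coloured by the treatment field. ATF3 lay at 849 and 1193 in the Ribo-seq libraries titled i14G1-10, and at 888 and 924 in the Ti-seq libraries titled i14G1-12, the 4 libraries whose treatment field reads i14G1-12.

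In libraries titled i14G1-10, stress and immediate early transcripts were higher than in libraries titled Control. DNAJB1, an HSP40 co-chaperone, rose by 2.0 ± 0.19 log2 units (adjusted p = 0.000143). CHAC1, a glutathione-degrading enzyme induced by ATF4, rose by 1.71 ± 0.18, and DDIT3, the gene of CHOP, by 1.92 ± 0.24. ATF3 rose by 1.82 ± 0.23 and PPP1R15A, the stress-induced phosphatase subunit GADD34, by 1.70 ± 0.21. ZFAND2A (1.87 ± 0.23), IER2 (1.65 ± 0.19) and DUSP1 (1.56 ± 0.23) completed the 8 largest rises among called genes that moved the same way in both arms. LDHA (a change of -1.66 ± 0.31), EID1 (-1.58 ± 0.29), CPVL (-1.22 ± 0.25), OLA1 (-1.21 ± 0.26), ATP5A1 (-1.18 ± 0.22) and GYG1 (-1.10 ± 0.23) fell. CHAC1 changed by 0.11 ± 0.26 in Ribo-seq and 3.32 ± 0.26 in Ti-seq, a difference that passed its own test. In all, 48 of 6813 genes were called, 42 higher and 6 lower, of which 44 moved in the same direction in both arms. Calls rest on the mean of the differences within the arms, so agreement in direction is partly built in, here and in the comparisons below.

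By list, 13 of 22 immediate early genes rose in the libraries titled i14G1-10 (15 adjusted over the list alone), as did 8 of 23 ATF4 and CHOP targets (12 adjusted over the list alone). So did 5 of 19 heat shock genes (5 adjusted over the list alone). The adjusted camera p was 1.49e-20, 3.62e-12 and 9.71e-07, and with an estimated correlation the adjusted p was 0.0295, 0.022 and 0.022. HSPA6, a strictly inducible HSP70, rose by 2.56 on average, with 5.60 ± 0.65 in Ribo-seq and -0.48 ± 0.65 in Ti-seq. BAG3 rose by 1.32 and HSPA1B by 1.11. Among unstable transcription regulator mRNAs 6 of 26 rose (11 adjusted over the list alone), with ID1 up by 1.38 and ID3 by 1.08. Of 12 p53 targets 3 rose (3 adjusted over the list alone), SESN2 by 1.10, BBC3 by 1.09 and CDKN1A by 0.91. Neither of these 2 lists was called with an estimated correlation (adjusted p = 0.155 for both). The lists of G2 and M phase (29 genes, 0 called, median -0.34) and of nuclear-encoded OXPHOS subunits (36 genes, 1 lower, median -0.24) were called lower, and not with an estimated correlation (adjusted p = 0.252 and 0.734). ATF4 (0.40 ± 0.16), HSPA5 (-0.19 ± 0.48), EIF4G1 (-0.05 ± 0.21) and EIF1 (-0.02 ± 0.15) did not pass.

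Grouped by the treatment field, 24 of the 48 calls by title were called in the opposite direction for i14G1-10 against DMSO, and the other 24 were not called. In Ti-seq both groupings compare the same libraries here, with the sides swapped. Those differences change sign by construction (a correlation of -1 across genes). DDIT3 (-3.10 ± 0.24), CHAC1 (-3.09 ± 0.18, adjusted p = 1.7e-07), ATF3 (-2.30 ± 0.23), HMOX1 (-2.16 ± 0.19), HSPA1B (-2.04 ± 0.22), STC2 (-1.94 ± 0.25), SESN2 (-1.85 ± 0.20) and GCLM (-1.68 ± 0.25) were the 8 largest falls. PPP1R15A changed by -1.30 ± 0.21. ATP5A1 (1.26 ± 0.22) and OLA1 (1.25 ± 0.26) rose. There were 35 calls, 2 higher and 33 lower, all 35 in the same direction in both arms. Of the ATF4 and CHOP targets 10 of 23 fell (17 adjusted over the list alone), with a camera adjusted p of 3.3e-20 and, with an estimated correlation, 0.0106. SLC3A2, a subunit of the cystine transporter, was among them with a change of -1.68. The lists of NRF2 targets (3 of 16 lower, 5 adjusted over the list alone) and immediate early genes (6 of 22 lower; adjusted over the list alone, 9 lower and 3 higher) were called lower. So were unstable regulator mRNAs (6 of 26 lower; adjusted over the list alone, 8 lower and 3 higher), heat shock genes (3 of 19 lower, 4 adjusted over the list alone) and glycolysis genes (0 of 20 called; adjusted over the list alone, 2 lower and 1 higher). None of these 5 was called with an estimated correlation (adjusted p = 0.159, 0.508, 0.508, 0.159 and 0.159). Their medians of -0.16, -0.2, -0.16, -0.12 and -0.14 were -0.07, -0.13, -0.07, -0.03 and -0.05 with equal totals, and -0.21, -0.46, -0.22, -0.08 and -0.27 under quantile scaling. HSPA6 (-0.17 ± 0.46), ZFAND2A (-0.97 ± 0.23), EGR1 (0.29 ± 0.37), ATF4 (-0.37 ± 0.16), HSPA5 (0.60 ± 0.48), EIF4G1 (-0.16 ± 0.21) and EIF1 (-0.11 ± 0.15) did not pass.

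The title-based count of 48 fell to 0 in an additive model of compound and arm (limma, 601 genes at an unadjusted p under 0.05) and was 29 with equal library totals, 29 with edgeR and 20 with only the compared groups. It was 188 without Control Ribo-seq 1, 30 without Control Ribo-seq 2, 18 without Control Ti-seq 1 and 24 without Control Ti-seq 2. It was 21 without i14G1-10 Ribo-seq 1, 89 without i14G1-10 Ribo-seq 2, 301 without i14G1-10 Ti-seq 2 and 31 without i14G1-12 Ti-seq 2. The field-based count of 35 was 22 with equal totals, 60 with edgeR and 125 with DESeq2. It was 165 without the library titled Control Ribo-seq 1, 23 without Control Ti-seq 1, 22 without Control Ti-seq 2, 382 without i14G1-10 Ti-seq 2 and 22 without i14G1-12 Ribo-seq 1. The balance turned without Control Ribo-seq 1 (by title 88 higher and 100 lower, by field 112 and 53) and without i14G1-10 Ti-seq 2 (by title 80 and 221, by field 294 and 88).

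For i14G1-12, the titles gave 5 called genes, all higher, and the calls differed between the arms. EGR1, an immediate early transcription factor, rose by 2.70 ± 0.37 (adjusted p = 0.0145), CYR61, a matricellular protein gene, by 2.05 ± 0.33, ZFAND2A by 1.47 ± 0.23, IER2 by 1.15 ± 0.19 and DNAJB1 by 1.10 ± 0.19. Of the 5, 1 moved in the same direction in both arms, CYR61 (0.25 ± 0.46 in Ribo-seq and 3.85 ± 0.46 in Ti-seq). ZFAND2A lies outside the naming rule and was chosen after its value was seen. EGR1 stood at 4.691 ± 2.18 in the Ribo-seq and 600.8 ± 5.43 in the Ti-seq libraries titled i14G1-12, against 4.907 ± 0.31 and 15.38 ± 13.7 in those titled Control. No gene fell, and the 3 with the smallest p were ATP5A1 (-0.77 ± 0.22), PIN4 (-0.73 ± 0.21) and SNRPD3 (-0.59 ± 0.16).

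Under the titles 3 of 22 immediate early genes were called for i14G1-12 (16 adjusted over the list alone, median 0.86) and 1 of 19 heat shock genes (4 adjusted over the list alone). Of the unstable regulator mRNAs 1 of 26 was called (9 adjusted over the list alone) and of the p53 targets 0 of 12 (3 adjusted over the list alone), and all 4 lists were called higher. With an estimated correlation the first 2 held (adjusted p = 0.0149 and 0.0146) and the others did not (adjusted p = 0.217 for both). OXPHOS subunits (median -0.17), G2 and M phase genes (median -0.11) and HEK293 lineage genes (median -0.25) were called lower with 0 single genes called, also adjusted over the list alone, and not with an estimated correlation (adjusted p = 0.662, 0.327 and 0.23). The OXPHOS median became -0.1 with equal totals and under quantile scaling, and that of G2 and M phase genes -0.05 and -0.09. PPP1R15A (1.17 ± 0.21, adjusted p = 0.0518), ATF3 (0.75 ± 0.23), DDIT3 (0.33 ± 0.24), HSPA5 (0.16 ± 0.48), ATF4 (0.11 ± 0.16), EIF4G1 (-0.11 ± 0.21) and EIF1 (-0.02 ± 0.15) did not pass.

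By the treatment field, i14G1-12 libraries showed a large rise of heat shock and immediate early transcripts over DMSO libraries. HSPA6 rose by 5.85 ± 0.46 log2 units (57.58-fold), EGR1 by 5.47 ± 0.37 (44.27-fold) and FOS by 4.09 ± 0.37. CYR61 rose by 3.83 ± 0.33, MAFF by 3.68 ± 0.52, ZFAND2A by 2.99 ± 0.23, HSPA1A by 2.94 ± 0.30 and FOSB by 2.75 ± 0.52. FABP5 (-2.64 ± 0.69), a fatty acid binding protein gene, and the histone genes HIST1H2BO (-2.0 ± 0.40), HIST1H2BK (-1.65 ± 0.25) and HIST1H2AI (-1.57 ± 0.38) were among the 8 largest falls. IBA57 (-1.65 ± 0.41), WASF2 (-1.43 ± 0.32), CLPTM1 (-1.30 ± 0.28) and RRBP1 (-1.28 ± 0.26) were the others. PPP1R15A rose by 2.14 ± 0.21 and ATF3 by 1.70 ± 0.23. There were 252 calls, 176 higher and 76 lower, all 252 in the same direction in both arms. They included the 5 calls of the titles in the same direction.

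Of the immediate early genes 19 of 22 rose under the field (20 adjusted over the list alone, median 1.8). Of the heat shock genes 9 of 19 rose (14 adjusted over the list alone), DNAJB1 by 2.54 and BAG3 by 2.03. Adjusted p with an estimated correlation was 0.0279 and 0.00549. Unstable regulator mRNAs (10 of 26 higher, 12 adjusted over the list alone, HES1 by 1.90) and p53 targets (5 of 12 higher; adjusted over the list alone, 5 higher and 1 lower) were called higher by camera, with BTG2 up by 1.96 and CDKN1A by 1.18. They were not called with an estimated correlation (adjusted p = 0.165 and 0.221). OXPHOS subunits (4 of 36 lower, 11 adjusted over the list alone, ATP5G1 by a change of -0.98) were called lower. So were HEK293 lineage genes (0 of 9 called, 4 lower adjusted over the list alone) and histones (2 of 7 lower, 3 adjusted over the list alone), all of these not with an estimated correlation (adjusted p = 0.424, 0.165 and 0.424). Their medians of -0.38, -0.37 and -0.46 were -0.2, -0.23 and -0.3 with equal totals and -0.18, -0.3 and -0.63 under quantile scaling. Large and small ribosomal subunit proteins (2 of 47 and 1 of 32 lower, 2 and 1 adjusted over the list alone) were called lower, adjusted p = 0.588 for both with an estimated correlation; the medians of -0.18 and -0.21 became -0.01 and -0.03 with equal totals and -0.01 and 0.06 under quantile scaling. Of the 23 ATF4 and CHOP targets 3 rose (3 adjusted over the list alone), among them CTH by 1.58, and the list was not called (adjusted p = 0.162). DDIT3 (0.62 ± 0.24), ATF4 (0.19 ± 0.16), HSPA5 (-0.12 ± 0.48), EIF4G1 (-0.02 ± 0.21) and EIF1 (0.00 ± 0.15) did not pass.

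The title-based count of 5 was 0 in the additive model (limma, 92 genes at an unadjusted p under 0.05), 10 with a pseudocount of 4 or quantile scaling, 3 with equal totals, 2 with only the compared groups and 13 with DESeq2. It was 16 without Control Ribo-seq 1, 3 without Control Ribo-seq 2, 1 without Control Ti-seq 1, 3 without i14G1-10 Ti-seq 2 and 2 without i14G1-12 Ribo-seq 1. It was 0 without each of i14G1-12 Ribo-seq 2, i14G1-12 Ti-seq 1 and i14G1-12 Ti-seq 2. The field-based 252 was 143 with library weights, 91 with only the compared groups, 423 with DESeq2 and 141 without the 2 libraries with most genes at 1 count. It was 664 without the library titled Control Ribo-seq 1, 145 without either of Control Ti-seq 1 and Control Ti-seq 2, and 163 without i14G1-10 Ribo-seq 2. It was 96 without i14G1-10 Ti-seq 1, 606 without i14G1-10 Ti-seq 2 and 60 without either of i14G1-12 Ti-seq 1 and i14G1-12 Ti-seq 2. The share of higher calls under the field, 69.8%, was 90.3% with equal totals, 51.9% with edgeR (140 higher, 130 lower) and 35.5% with DESeq2 (150 higher, 273 lower).

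The compounds were compared directly at the same time but at different doses, 10 µM for i14G1-12 and 20 µM for i14G1-10. By title, 3 ATF4 targets were lower with i14G1-12 than with i14G1-10: CHAC1 (-1.73 ± 0.18, adjusted p = 0.000594), DDIT3 (-1.59 ± 0.24) and SLC3A2 (-1.05 ± 0.17). CHAC1 and SLC3A2 differed in the same direction in both arms (2 of the 3 genes), and DDIT3 did not. Within the arms by title, 119 genes were called between the compounds in Ribo-seq (20 higher, 99 lower) and 79 in Ti-seq (65 higher, 14 lower). No gene was higher, and the 3 with the smallest p were SCD5 (1.36 ± 0.33), IGFBP5 (1.33 ± 0.33) and ANKS1A (1.25 ± 0.31). The list of ATF4 and CHOP targets was called lower (3 of 23, 13 adjusted over the list alone, adjusted p = 0.0355 with an estimated correlation), and that of NRF2 targets (0 of 16 called, 4 lower adjusted over the list alone) only with the preset correlation (adjusted p = 0.487 with an estimated correlation). ATF3 differed by -1.07 (95% interval -1.56 to -0.58) and PPP1R15A by -0.53 (-0.97 to -0.08), without passing. ATF4 differed by -0.28 (-0.62 to 0.05), HSPA5 by 0.35 (-0.67 to 1.37), EIF4G1 by -0.06 (-0.51 to 0.39) and EIF1 by 0.00 (-0.31 to 0.31), and none of these passed either.

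By the treatment field, heat shock, immediate early and ATF4 target transcripts were higher with i14G1-12. HSPA6 was higher by 6.02 ± 0.46 log2 units, EGR1 by 5.18 ± 0.37, FOS by 4.32 ± 0.37, and ATF3 by 4.01 ± 0.23 (16.06-fold). DNAJB1 was higher by 4.0 ± 0.19, DUSP1 by 3.99 ± 0.23, ZFAND2A by 3.96 ± 0.23 and MAFF by 3.93 ± 0.52. DDIT3 was higher by 3.72 ± 0.24, PPP1R15A by 3.44 ± 0.21, CHAC1 by 2.91 and ATF4 by 0.56 ± 0.16. LRRC58 (-2.13 ± 0.48), GAS1 (-2.06 ± 0.47), EID1 (-1.87 ± 0.29), HIST1H2BO (-1.76 ± 0.40), NEFL (-1.69 ± 0.26), C1GALT1C1 (-1.59 ± 0.40), HIST1H2BK (-1.54 ± 0.25) and IBA57 (-1.45 ± 0.41) were the 8 largest falls. There were 427 calls, 281 higher and 146 lower, all 427 in the same direction in both arms. The 3 calls of the titles were among them with the opposite sign. In Ribo-seq both groupings compare the same libraries here, with the sides swapped, so those differences change sign by construction. Within the arms there were 119 calls in Ribo-seq (99 higher, 20 lower) and 97 in Ti-seq (88 higher, 9 lower).

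Under the field 19 of 22 immediate early genes (adjusted over the list alone, 19 higher and 2 lower), 12 of 23 ATF4 and CHOP targets (14 adjusted over the list alone) and 11 of 19 heat shock genes (14 adjusted over the list alone) were higher with i14G1-12, with adjusted p = 0.0143, 0.00919 and 0.00268 with an estimated correlation. Unstable regulator mRNAs (12 of 26 higher; adjusted over the list alone, 12 higher and 1 lower) and p53 targets (6 of 12, 7 adjusted over the list alone; CDKN1A by 1.72, BBC3 by 1.75) were called higher. So were aminoacyl-tRNA synthetases (4 of 18, 4 adjusted over the list alone; CARS by 1.36) and autophagy genes (3 of 18; adjusted over the list alone, 5 higher and 1 lower; SQSTM1 by 1.08). OXPHOS subunits (6 of 36 lower, 12 adjusted over the list alone) and HEK293 lineage genes (1 of 9 lower, 3 adjusted over the list alone) were called lower. None of these 6 held with an estimated correlation (adjusted p = 0.0897, 0.0897, 0.118, 0.118, 0.427 and 0.118). Single members of other lists moved too, among them VEGFA (1.89), XBP1 (1.22), HMOX1 (1.74), PCNA (-0.92) and HIST1H2BD (-1.37). HSPA5 differed by -0.71 (95% interval -1.73 to 0.31), EIF4G1 by 0.14 (-0.31 to 0.60) and EIF1 by 0.11 (-0.20 to 0.42), without passing.

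The title-based count of 3 was 0 in the additive model (limma, 476 genes at an unadjusted p under 0.05), 5 with DESeq2 and 227 without i14G1-10 Ti-seq 2. It was 1 without each of i14G1-10 Ribo-seq 1, i14G1-10 Ti-seq 1, i14G1-12 Ribo-seq 1, i14G1-12 Ribo-seq 2, i14G1-12 Ti-seq 1 and i14G1-12 Ti-seq 2. The field-based 427 was 799 with library weights, 824 with only the compared groups, 829 without the 2 libraries with most genes at 1 count, 271 with DESeq2. It was 173 without the library titled Control Ti-seq 1, 177 without Control Ti-seq 2, 256 without i14G1-10 Ribo-seq 1 and 191 without i14G1-12 Ribo-seq 1. It was 224 without i14G1-12 Ribo-seq 2, 177 without i14G1-12 Ti-seq 1 and 165 without i14G1-12 Ti-seq 2. The share of higher calls under the field, 65.8%, was 78.9% with equal totals, 53.7% with library weights, 51% with only the compared groups and 50.7% without the 2 libraries. Without i14G1-10 Ti-seq 2 the titles gave 188 higher and 39 lower.

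**Figure D2:**
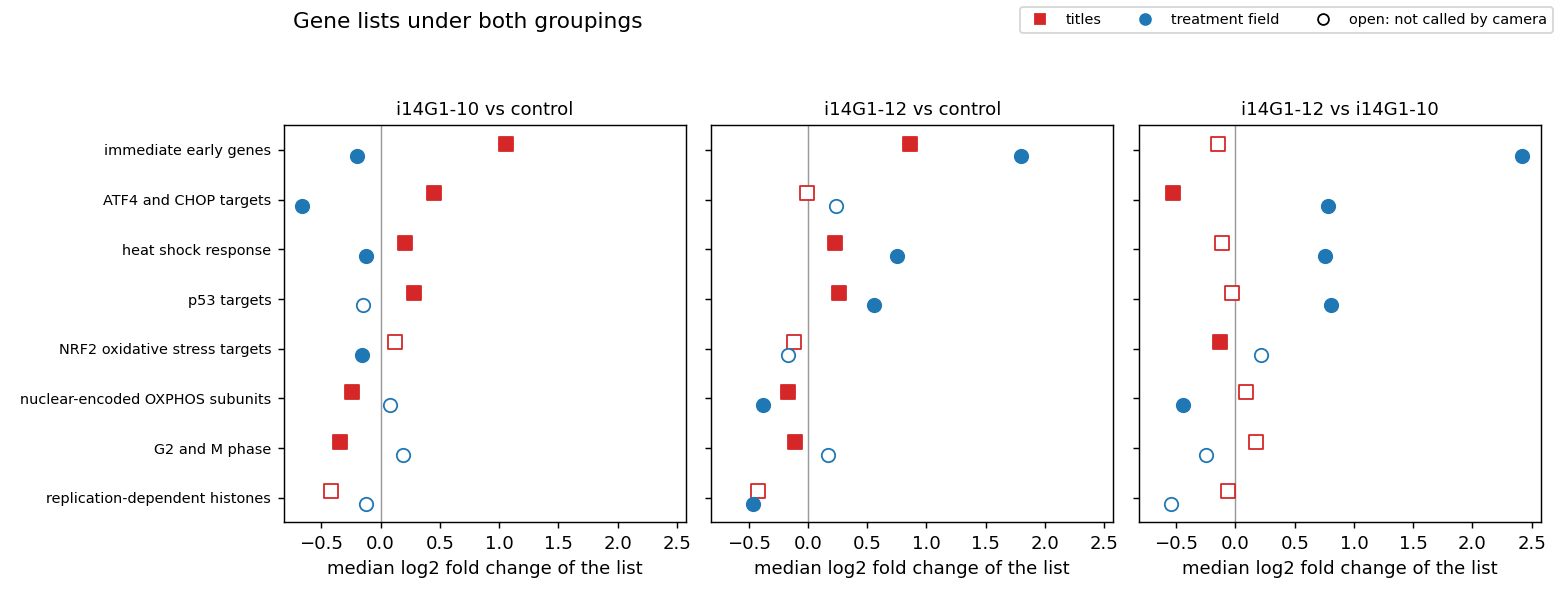
Median log2 fold change of 8 gene lists (rows) in the 3 compound comparisons (panels), grouped by titles (squares) and by the treatment field (circles), filled where camera with the preset correlation called the list. The median of ATF4 and CHOP targets for i14G1-10 against control was 0.45 by title and -0.66 by treatment field.

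Whether a compound's effect differed between the arms was tested directly. Under the titles, i14G1-12 against Control gave 88 genes with a compound-by-arm term, 80 with a higher and 8 with a lower difference in Ti-seq. CHAC1 changed by -2.87 ± 0.26 in the Ribo-seq arm and 2.84 ± 0.26 in the Ti-seq arm, a difference of 5.71 ± 0.36 (adjusted p = 5.41e-07). ATF3 changed by -2.5 ± 0.33 and 3.99 ± 0.33 in the same order, DDIT3 by -3.05 ± 0.34 and 3.71 ± 0.34, and DNAJB1 by -1.58 ± 0.27 and 3.77 ± 0.27. The ATF4 and CHOP targets (11 of 23, 15 adjusted over the list alone), immediate early genes (15 of 22; adjusted over the list alone, 17 higher and 2 lower) and heat shock genes (5 of 19, 9 adjusted over the list alone) had higher differences in Ti-seq, with adjusted p = 0.00332, 0.0163 and 0.00332 with an estimated correlation. The 8 genes with a lower difference were IMP3, CENPW, HYAL2, NEFL, ATP5A1, GAS1, EID1 and MED11, chosen after their values were seen. For i14G1-10, 5 genes had such a term, CHAC1 (3.21 ± 0.36) and HMOX1 (2.80 ± 0.38) higher in Ti-seq, and EGR1 (-5.43 ± 0.73), CYR61 (-3.82 ± 0.65) and HSPA6 (-6.08 ± 0.92) lower, also named after their values were seen. The count of 88 was 144 without Control Ribo-seq 1, 55 without Control Ti-seq 1, 54 without Control Ti-seq 2, 56 without i14G1-12 Ti-seq 1 and 51 without i14G1-12 Ti-seq 2. The count of 5 was 71 without Control Ribo-seq 1, 232 without i14G1-10 Ti-seq 2 and 2 without i14G1-10 Ribo-seq 1. It was 3 without each of i14G1-10 Ribo-seq 2, i14G1-10 Ti-seq 1, i14G1-12 Ribo-seq 1, i14G1-12 Ribo-seq 2, i14G1-12 Ti-seq 1 and i14G1-12 Ti-seq 2.

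Under the treatment field 0 genes had a compound-by-arm term for i14G1-10 (limma, 210 at an unadjusted p under 0.05; 0 with edgeR, 1 with DESeq2) and 0 for i14G1-12 (357 at an unadjusted p under 0.05; 0 with edgeR and with DESeq2). Without the library titled i14G1-10 Ti-seq 2 these counts were 99 and 109, and without Control Ribo-seq 1 the second was 1. Across all tested genes, which are not independent replicates, the differences within the arms correlated at 0.01 (i14G1-10), -0.30 (i14G1-12) and -0.29 (between the compounds) by title, and at 0.38, 0.42 and 0.66 by treatment field.

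Within the Ribo-seq arm by title, 25 genes were called for i14G1-10 (25 higher) and 15 for i14G1-12 (15 lower), and within the Ti-seq arm 21 (15 higher, 6 lower) and 97 (88 higher, 9 lower). By treatment field the Ribo-seq arm had 15 calls for i14G1-10 (15 lower) and 25 for i14G1-12 (25 higher). The Ti-seq arm had 21 (6 higher, 15 lower) and 79 (65 higher, 14 lower). In Ribo-seq these are the comparisons of the titles with the compound names exchanged. The Ribo-seq count of 25 was 240 without Control Ribo-seq 1 and 14 without each of Control Ribo-seq 2, i14G1-12 Ti-seq 1 and i14G1-12 Ti-seq 2, by title. The Ribo-seq count of 15 was 62 without Control Ribo-seq 1, 3 without i14G1-12 Ribo-seq 1 and 9 without i14G1-12 Ribo-seq 2. The Ti-seq count of 21 was 490 without i14G1-10 Ti-seq 2, 37 without either Control Ribo-seq library (1 or 2), and 4 without Control Ti-seq 1 or i14G1-10 Ti-seq 1. It was 5 without Control Ti-seq 2, 13 without i14G1-12 Ribo-seq 1 or 2, and 12 without i14G1-12 Ti-seq 1 or 2. The Ti-seq count of 97 was 149 and 148 without Control Ribo-seq 1 and 2, 44 and 54 without Control Ti-seq 1 and 2, and 46 without i14G1-12 Ti-seq 1 or 2. The Ti-seq count of 79 was 211 and 217 without Control Ribo-seq 1 and 2, 41 without Control Ti-seq 1 or 2, and 120 and 121 without i14G1-10 Ribo-seq 1 and 2. It was 23 and 682 without i14G1-10 Ti-seq 1 and 2, and 14 and 20 without i14G1-12 Ti-seq 1 and 2. In the Ribo-seq arm the Control libraries carry the same treatment in both labels, and DNAJB1 stood there at 1813 ± 36.2, against 11480 ± 1620 in the libraries titled i14G1-10 and 607.9 ± 42.2 in those titled i14G1-12.

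The arms differed in 3120 of 6813 genes, 1349 higher and 1771 lower in Ti-seq, and neither grouping changes this comparison. RPS29, a small ribosomal subunit protein gene, changed by -6.79 ± 0.32 log2 units. It stood at 15790 ± 12100, 7332 ± 3220 and 14180 ± 1260 normalized counts in Ribo-seq libraries titled Control, i14G1-10 and i14G1-12, and at 129.2 ± 71.9, 86.6 ± 8.03 and 95.05 ± 32.7 in Ti-seq. NDUFA4, a respiratory chain subunit gene, changed by -4.34 ± 0.39, ZNF22 by -3.64 ± 0.32, FBXO5 by -3.58 ± 0.33, TAF7 by -3.53 ± 0.31, RPS27 by -3.47 ± 0.39, GNPAT by -3.40 ± 0.33 and VEZT by -3.30 ± 0.31. ZMIZ1 (2.74 ± 0.27), ARHGEF11 (2.52 ± 0.39), HERC1 (2.41 ± 0.29), the acetyltransferase gene EP300 (2.19 ± 0.25), TRRAP (2.11 ± 0.20), the arginine transporter gene SLC7A1 (2.04 ± 0.20) and PLBD2 (2.03 ± 0.21) were among the largest rises. Ribosomal protein genes held 26.2% to 27% of the normalized counts in the Ti-seq libraries and 31.7% to 41.1% in the Ribo-seq libraries.

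Of the large ribosomal subunit protein genes 33 of 47 fell and 1 rose (34 and 1 adjusted over the list alone), with RPL35A at -2.35 and RPL41 at -2.10, and of the small subunit genes 21 of 32 fell (22 adjusted over the list alone). OXPHOS subunits (17 of 36 lower, 2 higher; 18 and 2 adjusted over the list alone) and proteasome subunits (14 of 29 lower, 2 higher; the same 14 and 2 adjusted over the list alone) were called lower, with ATP5A1 at -2.41 and PSMC2 at -1.18. Immediate early genes (13 of 22 higher, 14 adjusted over the list alone) and unstable regulator mRNAs (10 of 26 higher, 10 adjusted over the list alone) were called higher, with DUSP1 at 1.75, FOS at 1.71, NR4A1 at 1.48 and TOB2 at 1.19. None of these 6 lists was called with an estimated correlation (adjusted p = 0.644, 0.644, 0.644, 0.644, 0.533 and 0.533 in this order). Single genes of uncalled lists fell too, among them the nucleolar genes NOP58 (-3.12) and NPM1 (-2.72), MTHFD2 (-3.03) and the tRNA synthetases RARS (-2.96), NARS (-2.76) and EPRS (-2.17). SQLE (-3.01) and HMGCS1 (-2.26) of cholesterol synthesis also fell, as did CDK1 (-2.24), HSP90B1 (-2.14), CHORDC1 (-2.61) and EIF4A2 (-2.52). CDKN1A (1.64), BAG3 (1.5), SYVN1 (1.5) and ABCC1 (1.65) rose. EIF1 rose by 0.40 ± 0.12 and HSPA5 by 1.03 ± 0.39. DDIT3 (-0.36 ± 0.20), ATF3 (-0.26 ± 0.19), ATF4 (0.12 ± 0.13), EIF4G1 (-0.03 ± 0.17) and PPP1R15A (0.02 ± 0.17) did not pass.

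With equal library totals the median change of all genes between arms moved from -0.07 to 0.21 and 2142 of 3198 calls were higher (67% against 43.2%). Under quantile scaling 54.6% of calls were higher. The medians of large and small subunit proteins, OXPHOS and proteasome genes, -0.69, -0.55, -0.37 and -0.37, were -0.40, -0.26, -0.09 and -0.09 with equal totals and -0.28, -0.18, -0.22 and -0.2 under quantile scaling. Those of immediate early genes and unstable regulator mRNAs, 0.54 and 0.55, were 0.82 for both and then 0.69 and 0.6.

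**Figure D3:**
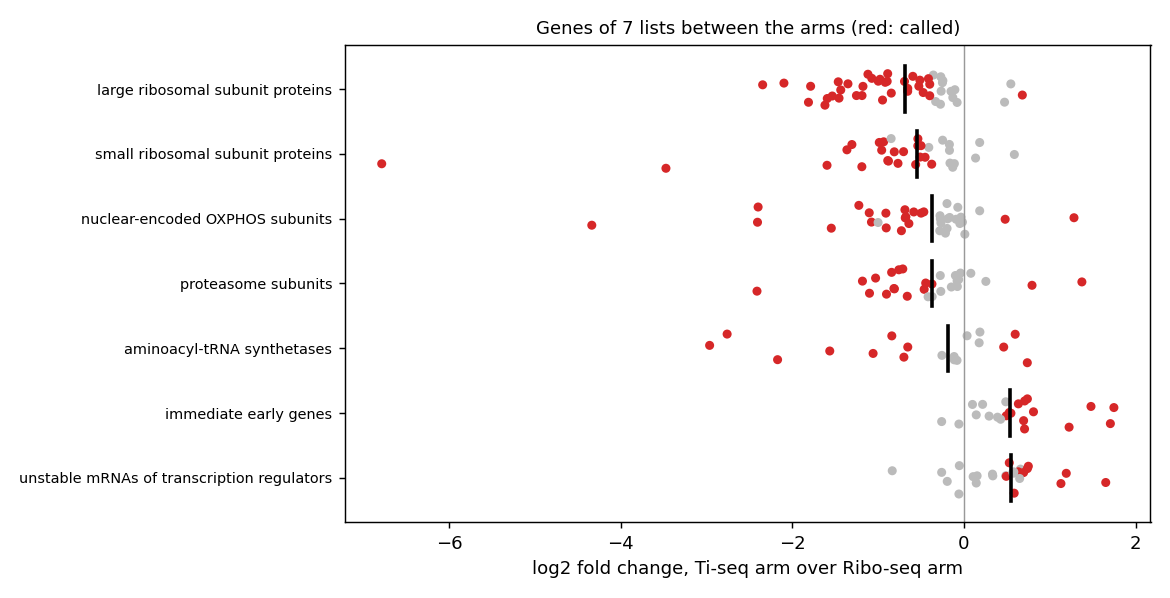
Log2 fold change of each tested gene of 7 lists between the Ti-seq and the Ribo-seq arm (points, red where called by limma, vertical position within a row random), with the median of the list as a black bar. The medians were -0.69 for large and -0.55 for small ribosomal subunit proteins, and 0.54 for immediate early genes.

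The fold changes of the 2 compounds against the shared control libraries correlated at 0.47 across genes by title (Spearman 0.39). Simulated unchanged groups, with the controls simulated too, gave 0.50. The simulation gave all groups the same spread for a gene, so a value near 0.50 follows from its design. The real groups differed in spread, so the simulated correlations and covariances do not test for a shared response. The covariance was 0.0556 against 0.0431 simulated, and with the controls split by replicate number the correlation was 0.03 in either assignment. By title 5 genes were higher with both compounds and 0 were lower with both. By treatment field the correlation was 0.37 (simulated 0.50), the covariance 0.0803 against 0.0434, and the split values -0.01 and 0.09. No call was shared by the compounds in the same direction under the field, and 15 genes were called in opposite directions.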

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

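Of the tests given here, the matching of groups between arms by the treatment field, its run with each library left out and the count of compounds of undisputed treatment were chosen only after the result was seen.

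Under the titles, the effect of a compound differed between the Ribo-seq and Ti-seq arms by a test of the difference itself. This held for 5 genes with i14G1-10 and for 88 genes with i14G1-12. CHAC1 had the smallest adjusted p with both (0.00152 and 5.41e-07). The 5 became 71 without Control Ribo-seq 1, 232 without i14G1-10 Ti-seq 2 and 2 without i14G1-10 Ribo-seq 1, and 3 without each of i14G1-10 Ribo-seq 2, i14G1-10 Ti-seq 1, i14G1-12 Ribo-seq 1, i14G1-12 Ribo-seq 2, i14G1-12 Ti-seq 1 and i14G1-12 Ti-seq 2. The 88 became 144 without Control Ribo-seq 1, 55 without Control Ti-seq 1, 54 without Control Ti-seq 2, 56 without i14G1-12 Ti-seq 1 and 51 without i14G1-12 Ti-seq 2.

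Over both compounds jointly, 189 genes had a compound-by-arm term under the titles. The tables argue against scaling of the deposited values and against low counts as the whole cause, since 221 genes had such a term after quantile scaling and 125 did among the 2595 genes with a mean of at least 100. A candidate explanation is that the treatment field, not the title, pairs the libraries of the arms: of the 6 ways to match the 3 Ribo-seq groups to the 3 Ti-seq groups, that of the field left 0 genes (limma), and the others 24, 80, 185, 189 and 233. The 0 stayed 0 with equal totals and quantile scaling, where the next lowest was 12 and 27. With each library left out it stayed 0, except without i14G1-10 Ti-seq 2, where the field left 95 genes jointly (99 for i14G1-10 and 109 for i14G1-12 singly) and the other matches 234 to 681. Such a match says which groups go together, not which compound each set received. It stays open whether the compounds act differently with harringtonine present: 0 compounds have an undisputed treatment in both arms, so this cannot be told apart from mistaken labels.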

How the results depend on the processing

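Chosen only after the data were seen were edgeR, DESeq2, the omission of the 2 libraries with most genes at 1 count, and every alternative run on groups from the treatment field. Alternatives are compared with the reported value by direction and side of the threshold, counts by whether they stay within 1.5 times. The count of the arm comparison stayed within that bound in all alternatives run (2474 with a mean of at least 20 to 3485 with edgeR) and with each library left out (2374 to 3408). Of the single genes followed under the titles, 77 kept direction and side of the threshold with a pseudocount of 0.5, 76 with a pseudocount of 4, 76 without the filter, 75 without robust moderation and 69 with a mean of at least 20. Under the treatment field these were 76, 74, 76, 75 and 64. With a mean of at least 20, followed genes below that mean were not tested. None of the rest lost a call or changed sign under either grouping, and 1 gained a call by title. In the additive model 45 kept direction and side under the titles and 32 lost their call, against 74 and 2 under the field. Other settings also cost calls, 9 by title and 10 by field with equal totals. It was 8 and 4 with library weights, 10 and 6 with only the groups compared, and 3 and 2 under quantile scaling.

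Under the titles, counts that moved by more than 1.5 times are given with the reported value in brackets. With a pseudocount of 4 the number of called genes was 10 (from 5) for i14G1-12 against control. With equal library totals it was 29 (from 48) for i14G1-10 against control, 3 (from 5) for i14G1-12 against control, 3 (from 5) for i14G1-10 against control by arm and 9 (from 21) for i14G1-10 against control within Ti-seq. Under quantile scaling it was 10 (from 5) for i14G1-12 against control. In the additive model it was 0 (from 48) for i14G1-10 against control, 0 (from 5) for i14G1-12 against control and 0 (from 3) for i14G1-12 against i14G1-10. With library weights it was 2 (from 5) for i14G1-10 against control by arm, 141 (from 88) for i14G1-12 against control by arm, 7 (from 25) for i14G1-10 against control within Ribo-seq, 113 (from 21) for i14G1-10 against control within Ti-seq and 873 (from 97) for i14G1-12 against control within Ti-seq. With only the groups compared it was 20 (from 48) for i14G1-10 against control, 2 (from 5) for i14G1-12 against control, 1 (from 5) for i14G1-10 against control by arm, 8 (from 21) for i14G1-10 against control within Ti-seq and 980 (from 97) for i14G1-12 against control within Ti-seq. Without the 2 libraries with most genes at 1 count it was 13 (from 21) for i14G1-10 against control within Ti-seq and 190 (from 97) for i14G1-12 against control within Ti-seq. With edgeR it was 29 (from 48) for i14G1-10 against control, 10 (from 5) for i14G1-10 against control by arm, 14 (from 25) for i14G1-10 against control within Ribo-seq, 33 (from 21) for i14G1-10 against control within Ti-seq and 184 (from 97) for i14G1-12 against control within Ti-seq. With DESeq2 it was 13 (from 5) for i14G1-12 against control, 5 (from 3) for i14G1-12 against i14G1-10, 72 (from 5) for i14G1-10 against control by arm, 142 (from 88) for i14G1-12 against control by arm and 118 (from 21) for i14G1-10 against control within Ti-seq. Further, it was 177 (from 97) for i14G1-12 against control within Ti-seq. With groups from the treatment field it was 252 (from 5) for i14G1-12 against control, 427 (from 3) for i14G1-12 against i14G1-10, 0 (from 5) for i14G1-10 against control by arm, 0 (from 88) for i14G1-12 against control by arm and 15 (from 25) for i14G1-10 against control within Ribo-seq. Further, it was 25 (from 15) for i14G1-12 against control within Ribo-seq. In Ribo-seq the field keeps the Control libraries and exchanges the compound names of the other groups, so these counts swap by construction. The additive model has a term for the arm, but keeps differences of a compound effect between the arms in its residual spread. With only the groups compared, fold changes stay as they were. The same holds for a comparison that includes neither of the 2 omitted libraries, here i14G1-12 against control within Ti-seq. Such counts move only through the estimate of the spread and its degrees of freedom. For the remaining moves the cause was not tested.

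Under the treatment field the counts moved as follows. With equal library totals the number was 22 (from 35) for i14G1-10 against control and 9 (from 21) for i14G1-10 against control within Ti-seq. With library weights the number was 143 (from 252) for i14G1-12 against control, 799 (from 427) for i14G1-12 against i14G1-10, 113 (from 21) for i14G1-10 against control within Ti-seq, 7 (from 25) for i14G1-12 against control within Ribo-seq and 342 (from 79) for i14G1-12 against control within Ti-seq. With only the groups compared the number was 91 (from 252) for i14G1-12 against control, 824 (from 427) for i14G1-12 against i14G1-10, 8 (from 21) for i14G1-10 against control within Ti-seq and 145 (from 79) for i14G1-12 against control within Ti-seq. Without the 2 libraries with most genes at 1 count the number was 141 (from 252) for i14G1-12 against control, 829 (from 427) for i14G1-12 against i14G1-10, 13 (from 21) for i14G1-10 against control within Ti-seq and 35 (from 79) for i14G1-12 against control within Ti-seq. With edgeR the number was 60 (from 35) for i14G1-10 against control, 33 (from 21) for i14G1-10 against control within Ti-seq, 14 (from 25) for i14G1-12 against control within Ribo-seq and 182 (from 79) for i14G1-12 against control within Ti-seq. With DESeq2 the number was 125 (from 35) for i14G1-10 against control, 423 (from 252) for i14G1-12 against control, 271 (from 427) for i14G1-12 against i14G1-10, 1 (from 0) for i14G1-10 against control by arm and 118 (from 21) for i14G1-10 against control within Ti-seq. Further, the number was 339 (from 79) for i14G1-12 against control within Ti-seq. With only the groups compared, fold changes stay as they were. The same holds without the 2 libraries for i14G1-12 against i14G1-10, since the field of both reads DMSO. Such counts move only through the estimate of the spread and its degrees of freedom. For the remaining moves the cause was not tested. The count tests had 11 libraries in place of 12.

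For lists, with an estimated correlation the number of called lists by title was 3 (from 7) for i14G1-10 against control, 2 (from 7) for i14G1-12 against control, 1 (from 2) for i14G1-12 against i14G1-10 and 0 (from 6) for the arms. With fry the number of called lists by title was 2 (from 7) for i14G1-12 against control, 1 (from 2) for i14G1-12 against i14G1-10 and 18 (from 6) for the arms. With groups from the treatment field the number of called lists by title was 9 (from 2) for i14G1-12 against i14G1-10. With an estimated correlation the number by treatment field was 1 (from 6) for i14G1-10 against control, 2 (from 9) for i14G1-12 against control and 3 (from 9) for i14G1-12 against i14G1-10. With fry the number by treatment field was 3 (from 6) for i14G1-10 against control. By construction fry does not compare a list with other genes; for the others the cause was not tested. For the shared response, the correlation of 0.47 was 0.03 with the controls split by replicate number in either assignment, where the compounds no longer share control libraries. It was 0.37 with groups from the treatment field.

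Changes of sign by title were these, on the log2 scale. With equal library totals the changes were EIF1 0.01 for i14G1-10 against control, EIF1 0.04 for i14G1-12 against control, EIF1 0.04 for i14G1-12 against i14G1-10, ATF3 0.03 and EIF4G1 0.26 for the arms. Under quantile scaling the changes were HSPA5 0.08 and EIF1 0.06 for i14G1-10 against control, EIF1 0.1 for i14G1-12 against control, HSPA5 -0.01, EIF4G1 0.03 and EIF1 0.04 for i14G1-12 against i14G1-10, EIF4G1 0.06 for the arms. Without the 2 libraries with most genes at 1 count the changes were HSPA5 -0.16 for i14G1-12 against control, EIF4G1 0.04 for i14G1-12 against i14G1-10, PPP1R15A -0.04 for the arms. With edgeR the changes were HSPA5 0.26 and EIF1 0.03 for i14G1-10 against control, HSPA5 -0.19 and EIF4G1 0.14 for i14G1-12 against i14G1-10, EIF4G1 0.16 for the arms. With DESeq2 the changes were HSPA5 0.28 and EIF1 0.04 for i14G1-10 against control, HSPA5 -0.16 and EIF4G1 0.14 for i14G1-12 against i14G1-10, EIF4G1 0.21 for the arms. With groups from the treatment field the changes were DDIT3 -3.1, ATF3 -2.3, PPP1R15A -1.3, ATF4 -0.37, HSPA5 0.6 for i14G1-10 against control. There too they were LDHA 1.37, EID1 1.3, CPVL 1.1, OLA1 1.25, ATP5A1 1.26, GYG1 0.55, and DNAJB1 -1.46, ZFAND2A -0.97, CHAC1 -3.09, IER2 -1.04, DUSP1 -1.57, HSPA6 -0.17, BAG3 -1.08, HSPA1B -2.04 and ID3 -0.83. With the same groups they were HSPA5 -0.12 and EIF1 0 for i14G1-12 against control, and DDIT3 3.72, ATF3 4.01, PPP1R15A 3.44, HSPA5 -0.71, ATF4 0.56, EIF4G1 0.14, EIF1 0.11, CHAC1 2.91 and SLC3A2 1.92 for i14G1-12 against i14G1-10. By treatment field the following changed sign. With equal library totals they were HSPA5 0 and EIF4G1 0.16 for i14G1-12 against control. Under quantile scaling they were EIF4G1 0.13 for i14G1-12 against control. Without the 2 libraries with most genes at 1 count they were EIF4G1 0.02 for i14G1-10 against control, EIF4G1 0.16 and EIF1 -0.11 for i14G1-12 against control. With edgeR they were HSPA5 0.16 and EIF1 -0.03 for i14G1-12 against control, EIF4G1 -0.09 for i14G1-12 against i14G1-10. With DESeq2 they were HSPA5 0.22 and EIF1 -0.03 for i14G1-12 against control, EIF4G1 -0.08 for i14G1-12 against i14G1-10. The cause was not tested. The adjusted camera p under the field was 3.3e-20 for ATF4 and CHOP targets in i14G1-10 against control, 0.0213 for heat shock response in i14G1-10 against control, 0.179 for p53 targets in i14G1-10 against control, 0.000919 for immediate early genes in i14G1-10 against control. It was 0.723 for nuclear-encoded OXPHOS subunits in i14G1-10 against control, 0.147 for G2 and M phase in i14G1-10 against control, 0.00293 for unstable mRNAs of transcription regulators in i14G1-10 against control, 0.838 for G2 and M phase in i14G1-12 against control. It was 7.98e-17 for ATF4 and CHOP targets in i14G1-12 against i14G1-10 and 0.0502 for NRF2 oxidative stress targets in i14G1-12 against i14G1-10. Part of these changes follows from the labels. For i14G1-10 against control in Ti-seq, and between the compounds in Ribo-seq, both groupings compare the same libraries with the sides swapped. Those differences change sign by construction, and elsewhere the libraries compared differ.

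With each library left out in turn, the number of called genes by title was 18 to 301 for i14G1-10 against control, 0 to 16 for i14G1-12 against control, 1 to 227 for i14G1-12 against i14G1-10 and 2 to 232 for i14G1-10 against control by arm. It was 51 to 144 for i14G1-12 against control by arm, 14 to 240 for i14G1-10 against control within Ribo-seq, 4 to 490 for i14G1-10 against control within Ti-seq and 3 to 62 for i14G1-12 against control within Ribo-seq. It was 44 to 149 for i14G1-12 against control within Ti-seq. By treatment field the number was 22 to 382 for i14G1-10 against control, 60 to 664 for i14G1-12 against control, 165 to 597 for i14G1-12 against i14G1-10 and 0 to 99 for i14G1-10 against control by arm. It was 0 to 109 for i14G1-12 against control by arm, 3 to 62 for i14G1-10 against control within Ribo-seq, 4 to 490 for i14G1-10 against control within Ti-seq and 14 to 240 for i14G1-12 against control within Ribo-seq. It was 14 to 682 for i14G1-12 against control within Ti-seq. The number of called lists for i14G1-12 against i14G1-10 was 1 to 2 by title and 7 to 12 by treatment field. Genes that changed sign without some library ranged, by title, from -0.66 to 0.28 for HSPA5 in i14G1-10 against control, -0.27 to 0.17 for EIF4G1 in i14G1-10 against control, -0.1 to 0.06 for EIF1 in i14G1-10 against control and -0.16 to 0.47 for HSPA5 in i14G1-12 against control. They ranged from -0.28 to 0.07 for EIF4G1 in i14G1-12 against control, -0.1 to 0.06 for EIF1 in i14G1-12 against control, -0.12 to 0.82 for HSPA5 in i14G1-12 against i14G1-10 and -0.28 to 0.16 for EIF4G1 in i14G1-12 against i14G1-10. They ranged from -0.03 to 0.03 for EIF1 in i14G1-12 against i14G1-10, -0.18 to 0.11 for EIF4G1 in the arms and -0.1 to 0.14 for PPP1R15A in the arms. By treatment field they ranged from -0.33 to 0.01 for EIF4G1 in i14G1-10 against control, -0.59 to 0.35 for HSPA5 in i14G1-12 against control, -0.24 to 0.2 for EIF4G1 in i14G1-12 against control and -0.07 to 0.08 for EIF1 in i14G1-12 against control. They ranged from -0.07 to 0.36 for EIF4G1 in i14G1-12 against i14G1-10. A group left with 1 library is assumed to vary like the others. Where the library left out belongs to no group of a comparison, the fold changes stay as they were. The count then moves only through the shared estimate of the spread and its degrees of freedom. For the other moves the cause was not tested.

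The share of higher calls moved as follows. For i14G1-10 within Ti-seq by title, 71.4% was 55.6% with equal totals, 33.6% with library weights (38 higher, 75 lower), 43.2% with the number within arm as a block and 87.5% with only the groups compared. By treatment field, 28.6% was 44.4%, 66.4%, 56.8% and 12.5%. Without i14G1-10 Ti-seq 2 there were 89 higher and 401 lower by title, and 401 and 89 by field. For i14G1-12 within Ti-seq by title, 90.7% was 52.8% with library weights (461 higher, 412 lower) and 50.3% with only the groups compared (493 and 487). By treatment field, 82.3% was 96% with equal totals, 97.1% without the 2 libraries with most genes at 1 count, 64.8% with only the groups compared, 58.2% with library weights, 45.1% with edgeR (82 and 100) and 31% with DESeq2 (105 and 234). Without Control Ribo-seq 1 it was 46.2% (from 100%) for i14G1-10 and 59.7% (from 0%) for i14G1-12 within Ribo-seq by title, and by field 59.7% (from 0%) and 46.2% (from 100%). For i14G1-10 by arm the 40% by title was 60% with edgeR and 83.3% with DESeq2. For the arms, 43.2% was 67% with equal totals, 54.6% under quantile scaling and 50.4% with DESeq2. The cause was not tested. Equal totals moved the median change of all genes by treatment field from 0.01 to 0.18 for i14G1-12 against control.

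The replicate numbers were not taken to pair the groups, since the labels give no shared day or batch and not every pair of groups deviated together: over 15 pairs the deviations of replicate 1 from replicate 2 correlated at -0.24 to 0.34 across genes, with 4 over 0.1 and the highest between i14G1-10 Ribo-seq and i14G1-10 Ti-seq. A partial pairing stays open. With the replicate number as a block, the counts by title were 50, 6 and 4 for i14G1-10 and i14G1-12 against control and against each other, 5 and 87 by arm and 3105 for the arms. With the number within arm as a block the arms differed in 3023 genes, and i14G1-10 within Ti-seq had 37 calls (from 21) under either grouping, by title 16 higher and 21 lower (from 15 and 6); the cause was not tested.

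The alternative of raw-count tests for a table of raw counts was not run as planned, since the table holds normalized counts. Depth limits the genes seen: a gene without a count in even 1 library is absent, 604 genes fell below the filter, and i14G1-10 Ti-seq 1 had 916 genes at 1 count.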

Other observations

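The 3 corrections applied to the difference between the arms were chosen after the data were seen, with what each would show written down before its own result.

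For each compound comparison the 8 libraries were split in all 35 ways into groups of 4 and refitted with the arm as a term. Under the titles the real split called 0 genes for i14G1-10 against control (limma, 601 at an unadjusted p under 0.05), 0 for i14G1-12 (92) and 0 between the compounds (476), so 35 of 35 splits called as many in each by arithmetic alone, and these counts do not bear on chance. The highest other splits called 95, 25 and 300 genes. The split with 95 is that of the arms within its 8 libraries. The arm term then rests on the libraries titled i14G1-12. The split thus sets the arm difference of the libraries titled Control and i14G1-10 against that of those titled i14G1-12. The other 2 point to a structure of the samples that the treatment field names. The one with 25 joins Control Ribo-seq with i14G1-12 Ti-seq, against all libraries whose field reads i14G1-10. The one with 300 joins i14G1-10 Ribo-seq with i14G1-12 Ti-seq, which are all libraries whose field reads i14G1-12. Under the treatment field the real splits called 36, 342 and 493 genes, the highest others 2, 214 and 0, and 1 of 35 splits, the real one, called as many in each. No share under 1 of 35 can be reached, and the libraries of a group may share a culture. Splits that part such libraries are then not comparable with the real split, which keeps them together, so the splits do not exclude chance.

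For the arms, the real split of the 12 libraries called 2697 genes in the same kind of fit. Of 100 splits 1, the real one, called as many, and the highest other called 1372. The other splits were drawn at random, can part libraries of a group that may share a culture, and leave the arm difference in the residual spread. They therefore do not exclude chance, and do not bear on a difference in handling.

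Technical explanations of the difference between the arms were tested with 3 corrections. After each library's trend on the GC content of the last 500 nt was removed, 82.1% of the genes called between the arms stayed called (2536 of 3089), and after that on transcript length 88.2% (2723 of 3089). Across genes the change between arms correlated with GC content at a Spearman rho of 0.32 and with length at 0.18. With ribosomal protein genes left out and totals of the rest set equal, 90.1% of the other genes stayed called in the same direction (2753 of 3057). The tables thus argue against the share of ribosomal protein counts as the whole cause. For GC content and transcript length they do so only for the values used, those of the longest annotated protein-coding transcript of a gene. That transcript, 7062 nt for RPS29, may not be the one expressed, so an effect of the true length or GC content stays open. Harringtonine is a biological candidate explanation that the design gives, but the labels name no processing batch, and a difference in handling between the arms was not tested.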
